A study of Mus musculus with 6 samples.

How the data were processed

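The data are RNA-seq libraries from c-kit+ bone marrow cells of 6 C57BL/6 mice with leukaemia at the end point, 3 with Gata2+/+ and 3 with Gata2+/f. Per the labels' protocols, thawed marrow was sorted, RNA was extracted with Trizol and a column kit, and poly-A selected libraries were made with a stranded TruSeq kit. The submitters' processing notes name CASAVA 1.8.2, STAR 2.5.4a, RSEM 1.3.0 and the mouse build GRCm38. The deposited values are RSEM expected counts, that is, estimated read counts per Ensembl gene, with 1 column per library and no normalization; 11.7% of the values were not whole numbers. Neither the annotation release nor the strand setting of the counting is stated, so genes that overlap on opposite strands are uncertain, and so are members of multigene families, whose shared reads RSEM divides by its model.

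The table held 43629 gene IDs. Symbols, positions and chromosomes came from the GENCODE M21 annotation of GRCm38, which held 42548 of the IDs (97.5%); the 1081 unmatched IDs held 0.336% to 0.390% of a library's counts and stayed in the tests under their IDs. Expected counts were rounded to whole numbers. Library totals ranged from 53789568 to 67854631, at which 3 counts correspond to 0.0424 to 0.0600 CPM. No pair of libraries was a duplicate of another (chi-square per gene 247 or more). Intervals on counts cover counting error only.

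Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10, in R 4.3.3), which left 15432. Libraries were scaled by TMM, with factors from 0.821 to 1.11, and CPM use these factors. Gata2+/f was compared with Gata2+/+ by edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, two-sided, no covariate), with Benjamini-Hochberg adjustment over all tested genes and a threshold of adjusted p under 0.05. Log2 fold changes and their standard errors come from that model. Its prior degrees of freedom were 3.57 and the common biological coefficient of variation was 0.483. The median log2 fold change of all genes was 0.019 with TMM, 0.031 with DESeq2's size factors and 0.11 with upper quartile factors, and the share of genes at an unadjusted p under 0.05 that were higher in Gata2+/f was 49.3%, 52.0% and 58.3%.

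The tests, 35 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Lists with 5 or more tested members were tested by camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over 34 lists; the sex-linked list only served to read the sex of the mice. Camera with an estimated correlation and fry were the alternatives. Members were also counted when adjusted over the list alone. Chromosomes were tested in the same way as 22 sets. The shift of a chromosome in a library is the median, over 9165 genes with a mean log2 CPM of 3 or more, of the deviation from each gene's median over the 6 libraries, with an interval from 500 bootstrap draws of genes; blocks along a chromosome held 25 consecutive genes. Named in the text are Gata2; up to 10 higher and 10 lower genes past the threshold, of which there were 0; the 10 genes with the smallest p; up to 4 members with the smallest p from each called list and each list of another cell type; and all members of the heptad and core binding factor lists. Any other name is given as chosen after its values were seen.

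Alternatives were DESeq2 1.42.0, limma voom with and without sample quality weights, robust empirical Bayes, other scalings, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, thresholds of 0.01 and 0.1, a test against a log2 fold change of 1, leaving out sex-linked genes and receptor segments, a prior count of 0.5, and leaving out each library in turn. The newer form of edgeR's quasi-likelihood test, sex as a covariate and the lists without Gata2 were added after the data had been seen. The gene tests were tested on simulated data made from the means, library sizes and dispersions of these libraries, with 67 genes changed 2-fold, 67 changed 4-fold and 66 changed 16-fold among 15432. In a simulation with no change camera called 0 of 34 lists, and it called the 1 list that was then moved. The simulated genes were drawn independently, so that check leaves out the correlation between genes of a list. In these libraries the estimated correlation was 0.72 for the proliferation list and 0.77 for the late neutrophil list. The check therefore cannot show whether calls with the preset correlation hold for such lists. Groups of 3 are too small for an outlier test, so none was made.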

Results

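RNA was sequenced from c-kit+ bone marrow cells of mice with end-stage leukaemia. All mice carried a Cbfb-MYH11 knockin allele, the fusion gene that an inversion of chromosome 16 creates in human acute myeloid leukaemia. The sorted cells bear Kit, the stem cell factor receptor, and came from marrow that had been frozen and thawed. The 6 libraries, 1 per mouse, formed 2 groups of 3. Replicates 3, 5 and 6 had both Gata2 alleles intact (Gata2+/+), and replicates 7, 9 and 11 had 1 allele with the change that the labels write as f (Gata2+/f). Total expected counts were 60931629, 56986464 and 67046503 for Gata2+/+ replicates 3, 5 and 6, and 67854631, 53789568 and 62995422 for Gata2+/f replicates 7, 9 and 11. The most abundant gene took between 1.58% and 2.13% of a library. The comparison asks how leukaemia that arises with reduced Gata2 differs in expression from leukaemia with 2 intact Gata2 alleles.

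Gata2, a zinc finger transcription factor of blood stem cells, progenitors and mast cells, was lower in each of the 3 Gata2+/f libraries than in any Gata2+/+ library. Its gene lies on chromosome 6 of GRCm38, from position 88193891 to 88207032 on the forward strand. The mean was 837 ± 86.5 CPM (counts scaled to library size; mean ± SD, n = 3 here and throughout) in Gata2+/+ and 345 ± 133 CPM in Gata2+/f, which is 41.3% of the Gata2+/+ level by the fitted model. The 3 Gata2+/f libraries had 498, 273 and 264 CPM (replicates 7, 9 and 11). The log2 fold change was −1.28 (SE 0.32; 95% interval −2.01 to −0.54), an interval that contains the −1 of a gene lowered to the output of 1 allele. It did not pass the threshold in edgeR's quasi-likelihood test (adjusted p = 0.109, Benjamini-Hochberg over all genes), and it did in DESeq2's Wald test (log2 fold change −1.26, adjusted p = 0.0143). The counts cover all exons of the gene, so they do not show what the f allele changes in it.

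The Gata2+/+ leukaemias resembled each other more than the Gata2+/f leukaemias did. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.955 to 0.964 within Gata2+/+, 0.925 to 0.938 within Gata2+/f and 0.887 to 0.944 between the groups. On the first principal component of the 500 most variable genes, which held 52.6% of the variance, the Gata2+/+ libraries sat between −38.7 and −35.3. Gata2+/f replicates 7 and 9 lay at 66.4 and 40.6, and Gata2+/f replicate 11 lay in between, at 3.35.

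Among the 10 single genes with the smallest p were several neutrophil granule genes, near 20-fold higher in Gata2+/f. Ngp (neutrophilic granule protein, chromosome 9) had 55.5 ± 23.6 CPM in Gata2+/+ and 1106 ± 273 CPM in Gata2+/f, a log2 fold change of 4.32 (SE 0.44). Its chromosome 9 neighbours Ltf (lactoferrin) and Camp (the antimicrobial peptide cathelicidin) had log2 fold changes of 4.31 (SE 0.45) and 4.38 (SE 0.46), from 29.3 ± 12.2 to 579 ± 214 CPM and from 20.4 ± 10.2 to 426 ± 87.4 CPM. Itgb2l, an integrin beta chain gene on chromosome 16, went from 1.29 ± 0.347 to 25.8 ± 8.83 CPM (log2 fold change 4.32, SE 0.43), and S100a9, a calcium-binding protein of neutrophils and monocytes, from 70.5 ± 39.3 to 1650 ± 818 CPM (4.55, SE 0.57). Add2 (beta adducin, part of the red cell membrane skeleton) had the largest difference of the higher genes among the 10, at 0.532 ± 0.306 CPM in Gata2+/+ and 41.0 ± 11.7 CPM in Gata2+/f (log2 fold change 6.25, SE 0.61). Acp5 (tartrate-resistant acid phosphatase) and Prg2 (eosinophil major basic protein) were at 81.1 ± 6.51 and 15.7 ± 2.38 CPM in Gata2+/f, with log2 fold changes of 2.47 (SE 0.28) and 2.74 (SE 0.34). The remaining 2 were lower in Gata2+/f. Hs6st2, a heparan sulphate sulphotransferase gene on chromosome X, went from 22.9 ± 7.13 to 0.255 ± 0.216 CPM (−6.48, SE 0.77), and Khnyn, a gene of an antiviral endoribonuclease-like protein on chromosome 14, from 191 ± 17.2 to 55.3 ± 10.02 CPM (−1.79, SE 0.22). For all 10, the 3 libraries of one group lay above the 3 of the other.

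None of these genes passed adjusted p under 0.05 in edgeR's quasi-likelihood test: adjusted p was 0.0509 for Add2, Itgb2l, Ngp, Ltf and Camp, 0.0747 for Acp5 and 0.0798 for Hs6st2, Khnyn, S100a9 and Prg2. Of 15432 genes tested, 0 were called higher and 0 lower. At an unadjusted p under 0.05 there were 3486 genes, 1718 higher and 1768 lower in Gata2+/f, where 771.6 would be expected by chance. DESeq2 called 1724 genes (912 higher, 812 lower), and the newer bias-adjusted form of edgeR's quasi-likelihood test called 32 (13 higher, 19 lower), all 32 among DESeq2's. The groups did not overlap for 4588 genes (29.7%, against 10% by chance for 3 against 3), of which 2024 were higher and 2564 lower in Gata2+/f. In counts simulated with the spread of these libraries, edgeR recovered 5.97% of 2-fold, 37.3% of 4-fold and 95.5% of 16-fold changes with 8 false calls, and DESeq2 recovered 13.4%, 70.1% and 100% with 89 false calls. Leaving out Gata2+/f replicate 11 gave 10 higher and 56 lower genes in edgeR's test.

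**Figure D1:**
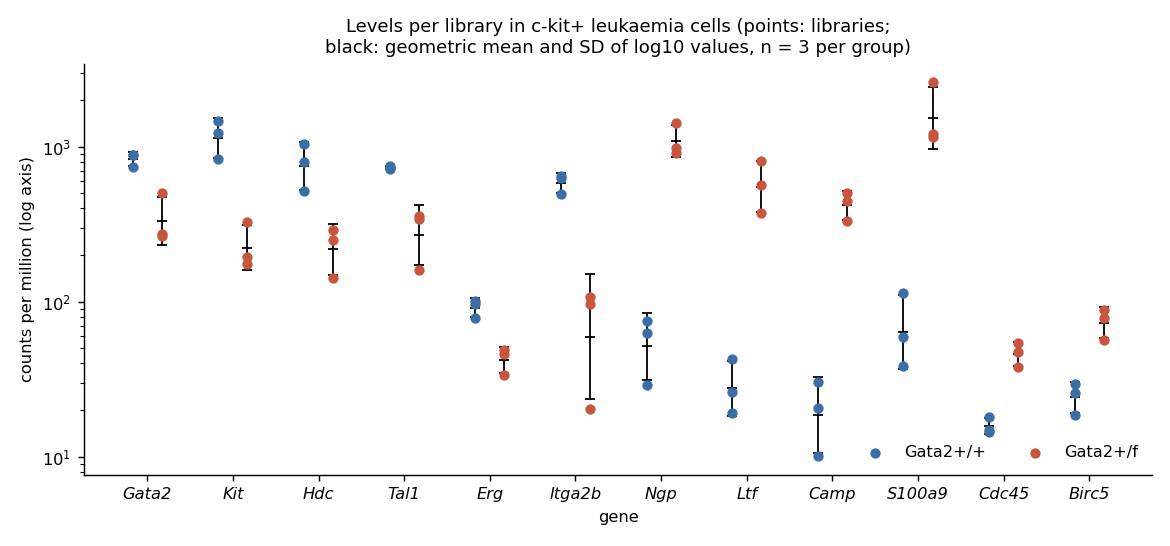
CPM on a log axis for 12 genes in each library, with Gata2+/+ in blue and Gata2+/f in red; points are libraries, and black marks are the geometric mean and the SD of log10 values (n = 3). Gata2 lay between 737 and 887 CPM in Gata2+/+ and between 264 and 498 CPM in Gata2+/f, while Ngp lay between 29.1 and 74.6 CPM in Gata2+/+ and between 913 and 1419 CPM in Gata2+/f.

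Genes of the late neutrophil list, which also holds granule genes such as Ngp, Ltf and Camp, were higher in Gata2+/f. Those of the early granulocyte list were less clearly so, and the lists were not tested against each other. All 27 members of the late neutrophil list had positive log2 fold changes, with a median of 2.86, and 23 passed the test when adjusted over the list alone (0 over all genes tested). The list was called higher by camera with a preset correlation (adjusted p = 1.82e-16), but not with an estimated one (adjusted p = 0.720 with an estimated correlation). Genes of earlier granulocytes and primary granules moved less uniformly: 15 of 19 were higher, with a median of 1.505 (camera adjusted p = 0.00664; adjusted p = 0.720 with an estimated correlation). Over this list alone 4 were higher and 1 lower, against 0 over all genes. Those 4 were Fcnb (ficolin B; 3.16 ± 2.36 against 50.1 ± 19.6 CPM, log2 fold change 3.98), Hp (haptoglobin; 2.18), Igsf6 (1.85) and Clec5a (2.17), and the 1 lower gene, chosen after its values were seen, was the protease inhibitor Serpinb1a (−1.66). The early granulocyte list was not called without Gata2+/f replicate 9 or without Gata2+/f replicate 11, where its adjusted p reached 0.0803; its median was 0.19 in Gata2+/+ replicate 5 and −0.19 in Gata2+/f replicate 7, relative to each gene's mean over the 6 libraries.

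Monocyte and dendritic cell genes were higher in Gata2+/f on average, though not in each library. Gata2+/+ replicate 5 and Gata2+/f replicate 9 lay close, with list medians of 0.18 and 0.19 for monocytes and 0.21 and 0.12 for dendritic cells (log2, relative to each gene's mean over the 6 libraries). Of 28 monocyte and macrophage genes 26 were higher, with a median log2 fold change of 1.55 (camera adjusted p = 9.53e-06; adjusted p = 0.720 with an estimated correlation). Irf8, the transcription factor that directs monocyte and dendritic cell development, was the 1 member that passed when adjusted over the list alone (0 over all genes), at 19.6 ± 11.1 CPM in Gata2+/+ and 81.7 ± 23.4 CPM in Gata2+/f (2.06, SE 0.43). Ms4a6c (1.90), Ly86 (2.05) and Cd300e (3.20) were the next by p and did not pass. For dendritic cells and antigen presentation, 20 of 21 genes were higher with a median of 1.34 (camera adjusted p = 6.90e-06; adjusted p = 0.720 with an estimated correlation), and 6 passed over the list alone (0 over all genes). They included Siglech, a receptor of plasmacytoid dendritic cells (0.261 ± 0.226 against 3.70 ± 1.74 CPM, log2 fold change 3.83), the cytokine receptor Flt3 (23.7 ± 1.62 against 59.9 ± 23.4 CPM, 1.34), and Clec9a (2.91) and Xcr1 (3.04) of cross-presenting dendritic cells. Siglech, Clec9a and Xcr1 stayed under 10 CPM in every library.

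Mast cell genes went the other way. Of 22 mast cell and basophil genes 19 were lower in Gata2+/f, with a median log2 fold change of −1.91 (camera adjusted p = 8.75e-06; adjusted p = 0.720 with an estimated correlation). Over this list alone 10 were lower and 1 higher, against 0 over all genes tested. Gata2+/f replicate 11 stood apart: relative to each gene's mean, the list median was 0.20 there, −2.21 and −1.27 in Gata2+/f replicates 7 and 9, and 0.91 to 1.44 in Gata2+/+. Kit itself, the receptor used for the sort, was at 1171 ± 323 CPM in Gata2+/+ and 232 ± 83.7 CPM in Gata2+/f (−2.34, SE 0.36, edgeR adjusted p = 0.0955). Hdc, which makes histamine, was at 785 ± 266 and 227 ± 77.1 CPM (−1.79, SE 0.38). The mast cell protease genes Mcpt4 and Tpsb2 were almost absent from Gata2+/f. Mcpt4 had 1620, 2140 and 56 counts in Gata2+/+ replicates 3, 5 and 6 against 1, 1 and 11 in Gata2+/f replicates 7, 9 and 11, a ratio of 335 (95% counting interval 196 to 630). Tpsb2 had 16, 892 and 161 counts against 0, 0 and 1, a ratio of 1220 (219 to 48236). These ratios depend on single libraries. With 1 library left out, that of Mcpt4 went from 223 (130 to 419, without Gata2+/+ replicate 5) to 1440 (398 to 11892, without Gata2+/f replicate 11). That of Tpsb2 went from 306 (54.2 to 12150, without Gata2+/+ replicate 5) to 1691 (303 to 66842, without Gata2+/+ replicate 3), and without Gata2+/f replicate 11 it had 0 counts left in Gata2+/f. Both belong to multigene families whose reads the counting may split, and the intervals cover counting error only. The 1 higher gene, chosen after its values were seen, was Prss34, a protease of basophils and mast cells (0.481 ± 0.296 against 3.55 ± 3.60 CPM).

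Some transcription factors that act with Gata2 in blood stem and progenitor cells were lower as well. In the heptad of Tal1, Lyl1, Lmo2, Runx1, Erg, Fli1 and Gata2, 5 of 7 were lower (median log2 fold change −1.10; camera adjusted p = 0.0351; adjusted p = 0.720 with an estimated correlation), and 4 passed over the list alone (0 over all genes). Tal1, the helix-loop-helix partner of Gata factors, was at 731 ± 14.4 CPM in Gata2+/+ and 284 ± 108 CPM in Gata2+/f (−1.36, SE 0.33), and the ETS factors Erg and Fli1 were at 91.8 ± 12.3 against 42.7 ± 7.88 CPM (−1.10) and 98.3 ± 17.5 against 54.3 ± 16.7 CPM (−0.86). The fourth was Gata2 itself, and without it the list of 6 was not called (median −0.98; camera adjusted p = 0.0993; adjusted p = 0.720 with an estimated correlation). Of these 6, 4 were lower and 3 passed over the list alone. Runx1, the DNA-binding partner of Cbfb, had 404 ± 94.4 and 167 ± 122 CPM with overlapping groups (−1.28), Lmo2 had 113 ± 17.9 and 155 ± 54.9 CPM (0.46), and Lyl1 had 125 ± 40.3 and 160 ± 40.4 CPM (0.36). In the core binding factor list 6 of 7 genes were lower (median −1.13; camera adjusted p = 0.0167; adjusted p = 0.720 with an estimated correlation). There Runx2, a partner of Cbfb best known from bone, was the 1 gene that passed over the list alone (190 ± 62.4 against 61.5 ± 22.2 CPM, −1.63; 0 over all genes), while Runx3 (−1.13), Runx1t1 (−2.91), Cbfa2t3 (−0.73) and Cbfa2t2 (−0.39) did not. Cbfb, which the knockin alters, was at 114 ± 22.4 and 134 ± 81.5 CPM (0.23, but −0.32 without Gata2+/f replicate 7 and 0.60 without Gata2+/f replicate 9). Its counts are per gene, so they do not separate the knockin allele from the intact one. The heptad was not called without Gata2+/+ replicate 5 or Gata2+/f replicate 9 or 11 (adjusted p up to 0.0845), nor the core binding factor list without Gata2+/f replicate 9 (0.0560).

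Of 9 Hoxa genes tested 7 were lower, with a median of −0.97, and the list did not pass (camera adjusted p = 0.0629). The result depended on the libraries used: relative to each gene's mean over the libraries, the list median was −2.33 in Gata2+/f replicate 9 but 0.59 and −0.057 in Gata2+/f replicates 7 and 11. The list was called without Gata2+/f replicate 7 (adjusted p = 0.00305) or Gata2+/+ replicate 3 (0.0198), with upper quartile factors (0.0391) or with a filter of 1 CPM in 3 libraries (0.0457), and its adjusted p was 0.495 without Gata2+/f replicate 9. The stem and early progenitor list, with a median of −0.089 over 27 genes, did not pass either (camera adjusted p = 0.881). In it 3 genes were lower over the list alone, Erg, the immediate early factor Egr1 (−3.03) and, chosen after its values were seen, the super elongation complex subunit gene Mllt3 (−1.62), and Flt3 was higher.

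Cell cycle genes were higher in Gata2+/f on average. All 48 proliferation genes had positive log2 fold changes, with a median of 1.22, and 40 passed when adjusted over the list alone (0 over all genes tested). The groups did not overlap for 40 of the 48. The list had the smallest p of all lists (camera adjusted p = 2.52e-18), again not with an estimated correlation (adjusted p = 0.720 with an estimated correlation). Cdc45, part of the replicative helicase, was at 15.8 ± 1.93 CPM in Gata2+/+ and 46.2 ± 8.01 CPM in Gata2+/f (1.55, SE 0.25). Birc5 (survivin) was at 24.6 ± 5.45 and 74.3 ± 16.1 CPM (1.60, SE 0.28), the spindle factor Tpx2 at 44.8 ± 11.9 and 110 ± 11.7 CPM (1.299, SE 0.25), and the mitotic kinase Plk1 at 14.97 ± 3.90 and 45.0 ± 10.6 CPM (1.59, SE 0.31). Within Gata2+/f, the list medians of proliferation (0.92, 0.48 and 0.31 in replicates 7, 9 and 11, relative to each gene's mean over the 6 libraries) ran in the opposite order to those of late neutrophil genes (0.63, 1.58 and 2.36).

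Growth and repair genes were higher on average by smaller amounts, and not in each Gata2+/f library. Gata2+/f replicate 11 lay near Gata2+/+ replicate 6, with list medians relative to each gene's mean of −0.144 and −0.143 for MYC and ribosome biogenesis, −0.023 and −0.077 for repair, and −0.056 and −0.091 for oxidative phosphorylation. The MYC and ribosome biogenesis list had 32 of 35 genes higher with a median of 0.59 (camera adjusted p = 9.53e-06; adjusted p = 0.720 with an estimated correlation). None of its members passed over the list alone or over all genes, including Nop2 (1.07), Nolc1 (1.06), Nop16 (1.06) and the spermidine synthase gene Srm (0.91). DNA damage and repair genes had a median of 0.39 (34 of 46 higher; camera adjusted p = 0.00351; adjusted p = 0.720 with an estimated correlation) and 0 members past the threshold over the list alone or over all genes. The DNA ligase gene Lig1 (1.03), Fancd2 (1.27) and the uracil glycosylase gene Ung (1.13) were among those with the smallest p. Oxidative phosphorylation genes had a median of 0.31 (47 of 54 higher; camera adjusted p = 0.00106; adjusted p = 0.720 with an estimated correlation), with 0 past the threshold over the list alone or over all genes. Atp5g1 (0.78), Ndufa5 (0.83) and Ndufa4 (0.73) lay higher, and Ndufa6 lay lower (148 ± 30.2 against 65.0 ± 12.5 CPM, −1.18). Ndufa6 lies on chromosome 15, whose genes as a whole were higher in Gata2+/+ replicates 3 and 6 (below). It had 176, 116 and 151 CPM in Gata2+/+ replicates 3, 5 and 6. In the cholesterol synthesis list 19 of 24 genes were higher (median 0.42; camera adjusted p = 0.0363; adjusted p = 0.720 with an estimated correlation). Fdps, which makes farnesyl diphosphate, was the 1 that passed over the list alone (21.4 ± 2.20 against 55.5 ± 17.4 CPM, 1.38; 0 over all genes), ahead of Mvd (1.42), Hsd17b7 (1.68) and Lss (−0.99). The repair list was not called without Gata2+/f replicate 7 (adjusted p = 0.115), nor the cholesterol list without Gata2+/+ replicate 5 or 6 or Gata2+/f replicate 9 or 11 (up to 0.176) or with sex as a covariate (0.0896).

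Markers of lymphoid cells were higher in Gata2+/f on average. Which cells of the sort carried them was not tested. In the B lineage list 15 of 16 genes were higher (median 1.45; camera adjusted p = 4.58e-05; adjusted p = 0.720 with an estimated correlation) and 6 passed over the list alone (0 over all genes). Jchain, the joining chain of secreted antibodies, was at 18.8 ± 3.13 and 55.2 ± 16.4 CPM (1.56), the immunoglobulin constant genes Ighm and Igkc had log2 fold changes of 1.9996 and 1.63, and the transcription factor gene Spib had 2.62. The T and NK lineage list had 17 of 19 genes higher (median 1.29; camera adjusted p = 0.00664; adjusted p = 0.720 with an estimated correlation). Over this list alone 0 were higher and 1 lower, against 0 over all genes. Klrd1 (2.54), Il2rb (2.67) and Cd8a (2.78) did not pass and were under 4 CPM in every library. This list was not called without Gata2+/f replicate 11 (adjusted p = 0.0783) or with a filter of 1 CPM in 3 libraries, which left 10 members (0.138). Its median was 0.018 in Gata2+/+ replicate 5 and −0.029 in Gata2+/f replicate 7, relative to each gene's mean. Interferon response genes had a median of 0.43, with 26 of 37 higher (camera adjusted p = 0.0363; adjusted p = 0.746 with an estimated correlation). None passed over the list alone or over all genes, among them Mx1 (2.26), Ifit1 (2.92), Bst2 (0.81) and Gbp7 (−1.03), and the list was not called without Gata2+/+ replicate 3 or 6 or Gata2+/f replicate 11 (adjusted p up to 0.522), or with the filter of 1 CPM (0.113). Its median of 0.31 in Gata2+/+ replicate 5 lay above those of Gata2+/f replicates 7 (−0.045) and 9 (−0.017).

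Erythroid, megakaryocytic, eosinophil and stromal markers did not pass as lists. Of 28 erythroid genes 19 were higher (median 0.82, camera adjusted p = 0.0732), and Add2 and Trim10, a gene needed for terminal erythropoiesis (1.13 ± 0.421 against 16.4 ± 7.40 CPM, 3.86), passed over the list alone (0 over all genes). Tfrc, the transferrin receptor, had a log2 fold change of 1.26. The erythroid list was called higher without Gata2+/+ replicate 3 (adjusted p = 0.0467) or 6 (0.0130). Its median relative to each gene's mean was high in Gata2+/f replicate 7 alone (1.05, against −0.083 and −0.019 in Gata2+/f replicates 9 and 11 and 0.12 in Gata2+/+ replicate 6). The abundant haemoglobin gene Hba-a2, chosen after its values were seen, went the other way without passing (4809 ± 1816 against 1768 ± 1652 CPM, −1.44). Megakaryocyte and platelet genes had a median of −0.033 (camera adjusted p = 0.701). Within them the integrin gene Itga2b (589 ± 82.4 against 74.7 ± 47.3 CPM, −2.98), the granule trafficking gene Rab27b (368 ± 16.8 against 68.8 ± 42.6 CPM, −2.42) and Timp3 (47.7 ± 51.3 against 0.393 ± 0.314 CPM, −6.92) were lower over the list alone and the adhesion receptor gene Selp was higher (2.03), with 0 over all genes. Eosinophil genes had a median of 0.46 (camera adjusted p = 0.119). Prg2, Epx (eosinophil peroxidase, 4.05) and Prg3 (2.05) were higher and Siglecf was lower (139 ± 42.0 against 29.8 ± 23.0 CPM, −2.23) over the list alone, with 0 over all genes. Stroma and endothelium genes had a median of 0.52, a mean of −0.031 and a camera adjusted p of 0.941, with 0 members past the threshold either way: Pdgfrb (−1.75), Kdr (2.30), Fabp5 (1.19) and Vwf (−2.32).

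Handling and heat shock stress genes, a sign of how cells were treated before lysis, were lower in Gata2+/f on average, with 21 of 24 genes lower and a median of −1.44 (camera adjusted p = 0.0138; adjusted p = 0.720 with an estimated correlation). Junb (962 ± 422 against 187 ± 65.2 CPM, −2.36), Egr1 (1814 ± 1698 against 222 ± 48.6 CPM, −3.03) and Jund (344 ± 171 against 95.7 ± 40.7 CPM, −1.85) passed over the list alone (0 over all genes), and Jun (4644 ± 2773 against 1346 ± 838 CPM, −1.79) did not. Without Gata2+/+ replicate 3, which had 3692 CPM of Egr1 against 1362 and 388 CPM in Gata2+/+ replicates 5 and 6, the median was −0.41 and the list was not called (adjusted p = 0.399). It was also not called without Gata2+/f replicate 9 (adjusted p = 0.0560), and relative to each gene's mean its median was −0.34 in Gata2+/+ replicate 6 and 0.0087 in Gata2+/f replicate 11. Of 34 lists tested, 12 were called higher and 4 lower with the preset correlation and 0 with an estimated one. Other splits of the 6 libraries, which mix the genotypes, called up to 16 lists with the preset correlation.

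**Figure D2:**
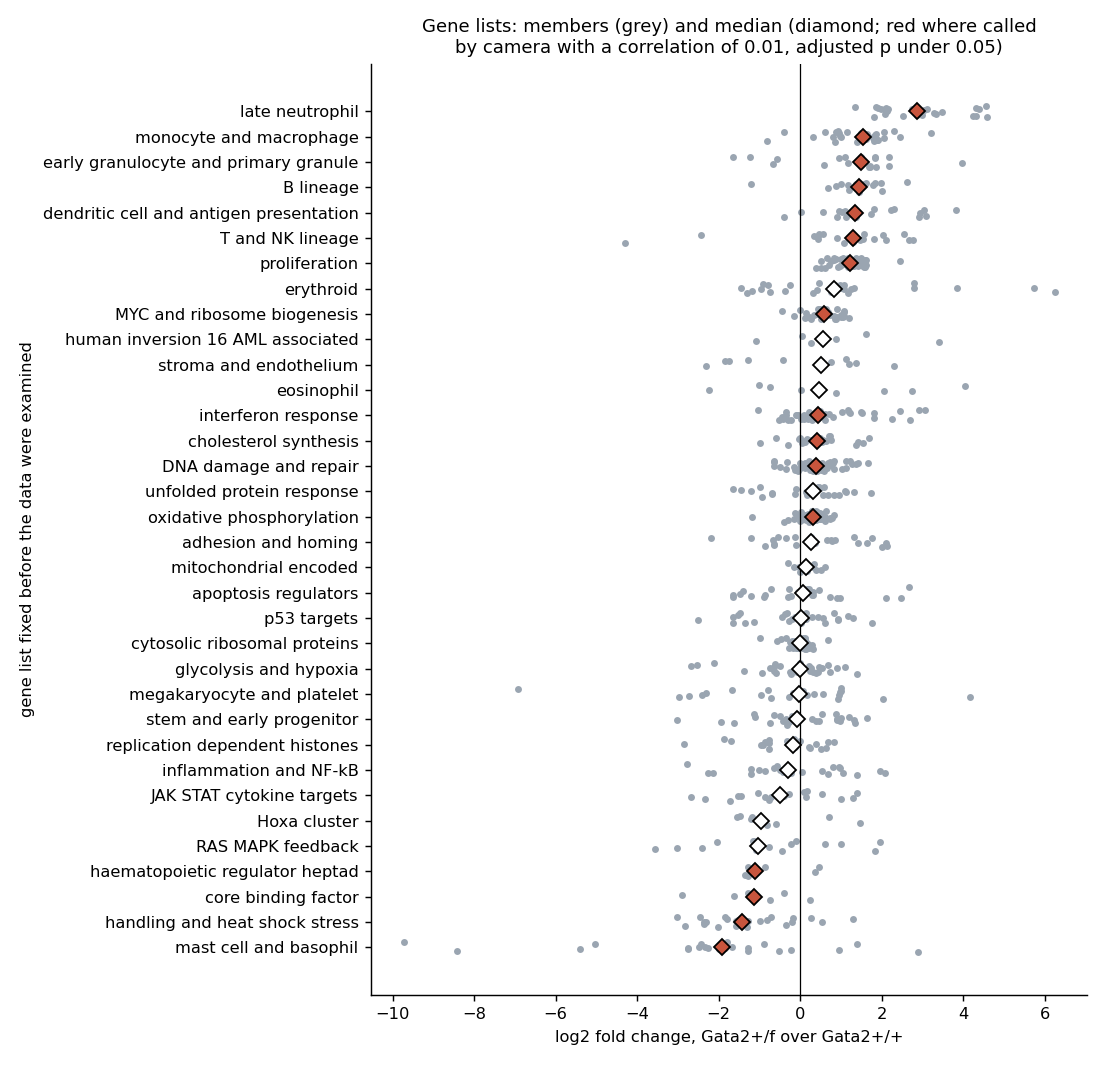
Log2 fold change (Gata2+/f over Gata2+/+) of each member (grey points) and the median (diamonds) of 34 gene lists, with red diamonds for the 16 lists called by camera at a preset correlation of 0.01. Late neutrophil genes lie highest, with a median of 2.86, and mast cell and basophil genes lowest, with a median of −1.91; no list was called with an estimated correlation.

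Xist and the Y-linked genes gave the sex of each mouse, and the groups were not balanced. Gata2+/+ replicate 3 and Gata2+/f replicates 7 and 9 had Y-linked transcripts and under 0.2 CPM of Xist, the RNA that silences 1 X chromosome in females, while Gata2+/+ replicates 5 and 6 and Gata2+/f replicate 11 had 1859, 1339 and 1287 CPM of Xist and 0 counts of Ddx3y, Eif2s3y, Kdm5d and Uty. With sex as a covariate, edgeR's test called 8 genes higher and 1 lower.

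Genes were also compared by chromosome, since a gain or loss of a chromosome in a leukaemia shifts its genes together. Chromosome 15 was lower in Gata2+/f: its 554 tested genes had a median log2 fold change of −0.30 (camera adjusted p = 0.0377; adjusted p = 0.983 with an estimated correlation), and it was the 1 of 22 called. The shift came from 2 of the Gata2+/+ libraries. Relative to each gene's median over the 6 libraries, genes of chromosome 15 lay 0.30 (95% bootstrap interval over genes 0.25 to 0.38) higher in Gata2+/+ replicate 3 and 0.32 (0.26 to 0.38) higher in Gata2+/+ replicate 6. In the other group, chromosome 8 lay 0.37 (0.30 to 0.42) higher in Gata2+/f replicate 7 and chromosome 18 lay −0.31 (−0.43 to −0.22) from the median in Gata2+/f replicate 9. These 4 of 120 pairs of chromosome and library passed 0.29, 0.5 of the log2 ratio of 3 copies to 2, and the largest other shift was 0.24 (0.17 to 0.33), of chromosome 6, which carries Gata2, in Gata2+/f replicate 9, with 52.9% of its blocks of 25 genes above that cutoff. Chromosome 15 was not called without Gata2+/+ replicate 3 or 6 or without Gata2+/f replicate 7 or 11 (camera adjusted p = 0.252, 0.567, 0.0652 and 0.148).

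**Figure D3:**
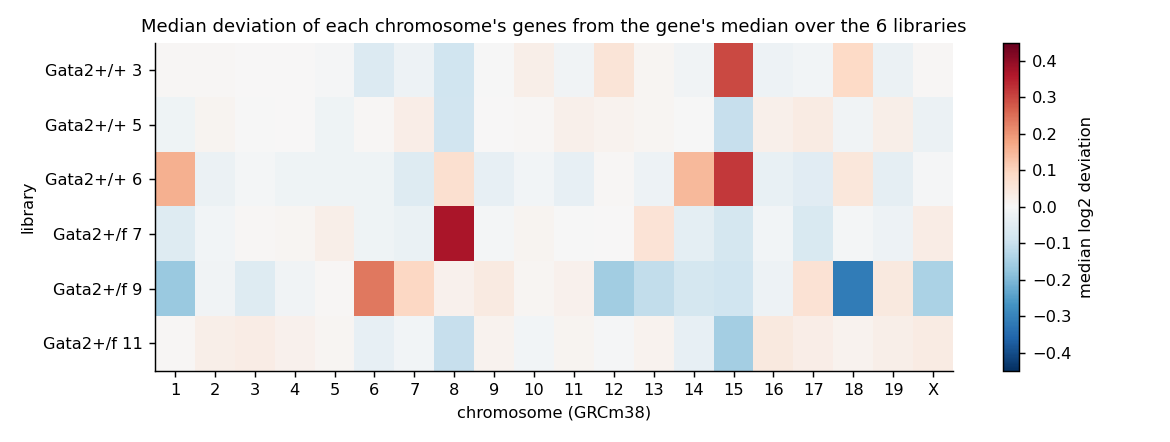
Median log2 deviation of the genes of each chromosome (columns, GRCm38) in each library (6 lines) from each gene's median over all libraries; red is above and blue below. Chromosome 15 stands at 0.30 and 0.32 in Gata2+/+ replicates 3 and 6, chromosome 8 at 0.37 in Gata2+/f replicate 7 and chromosome 18 at −0.31 in Gata2+/f replicate 9.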

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

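Of the alternatives here, the newer edgeR quasi-likelihood test, sex as a covariate and the lists without Gata2 were chosen only after the data had been seen. Gata2 was lower in Gata2+/f under each alternative run, with log2 fold changes of −1.60 to −1.07 when 1 library was left out, and passed the threshold in DESeq2 alone (−1.26). The counts were also 0 higher and 0 lower with DESeq2's size factors or upper quartile factors in edgeR, the stricter filter, robust empirical Bayes, a threshold of 0.01 and the test against a log2 fold change of 1. Calls appeared with DESeq2 (912 higher, 812 lower), limma voom (8 and 1), voom with sample quality weights (12 and 6), no filter beyond 1 count (10 and 9), a threshold of 0.1 (155 and 289), the newer quasi-likelihood test (13 and 19), sex as a covariate (8 and 1), and without sex-linked genes and receptor segments (5 higher). Leaving out 1 library gave 0 to 10 genes higher and 0 to 56 lower, with the highest counts without Gata2+/f replicate 11 and 1 lower gene without Gata2+/+ replicate 6. All 444 genes under an adjusted p of 0.1 were among DESeq2's calls. In the simulation with the spread of these libraries, DESeq2 made 89 false calls beside 9, 47 and 66 recovered 2-fold, 4-fold and 16-fold changes. The edgeR test made 8 beside 4, 25 and 63. These simulated rates need not hold in the real libraries, where edgeR called 0 genes higher and 0 lower. The cause of the differences between tests in the real libraries was not tested. Of the named genes, only Cbfb reversed, from 0.23 to −0.32 without Gata2+/f replicate 7. It was 0.60 without Gata2+/f replicate 9, the other end of its range. Cbfb lies on chromosome 8, whose genes lay 0.37 higher in Gata2+/f replicate 7 relative to each gene's median over the 6 libraries. The cause of the reversal was not tested. The 16 list calls became 0 with an estimated correlation and 0 with fry's directional test, 15 to 17 under other scalings, filters, the prior count and the sex covariate (the filter of 1 CPM ended the T and NK and the interferon calls, and the covariate the cholesterol call; the Hoxa list was called with that filter and with upper quartile factors), 15 without Gata2 in the lists, where the heptad was not called (adjusted p = 0.0993) and the mast cell list was (1.77e-05), and 11 to 17 when 1 library was left out. Late neutrophil, mast cell, monocyte, dendritic cell, B lineage, proliferation, MYC and oxidative phosphorylation lists were called in each of these 6 fits. The 1 chromosome call became 0 with an estimated correlation, with fry and without the filter, and 0 to 1 when 1 library was left out. The first principal component held 45.2% of the variance over all tested genes. No paired analysis was possible because the groups share no replicate numbers. Depth limits genes with few counts: at 3 counts per library the floor was 0.0424 to 0.0600 CPM, above the level of Tpsb2 in each Gata2+/f library.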

Other observations

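The tests of Kit against the stem cell and proliferation lists, of the neutrophil stage ratio, of a genotype effect on chromosome 15, of the heptad without Gata2 and of the count at an unadjusted p over splits were chosen only after the results they bear on had been seen.

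Several further mast cell genes, chosen after their values were seen, lay far apart between the groups. Cma1 (mast cell chymase) was at 2776 ± 554 CPM in Gata2+/+ and 66.1 ± 55.8 CPM in Gata2+/f (log2 fold change −5.39, SE 1.28; mean ± SD, n = 3), and Cyp11a1, a steroid-making enzyme also found in mast cells, at 260 ± 64.7 and 7.94 ± 9.65 CPM (−5.03, SE 1.251). Il1rl1, the receptor of interleukin 33 (1935 ± 301 against 602 ± 473 CPM, −1.68), the cytokine gene Il4 (62.1 ± 9.35 against 17.4 ± 12.5 CPM, −1.84) and the mast cell transcription factor gene Mitf (118 ± 9.02 against 21.9 ± 18.6 CPM, −2.43) were lower too. These 5 passed when adjusted over the list alone and not over all genes. Cpa3 (mast cell carboxypeptidase) varied within Gata2+/f, at 96.8, 151 and 1454 CPM in replicates 7, 9 and 11 against 2318 to 3690 CPM in Gata2+/+.

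Among lists that did not pass, some members did when adjusted over their list alone and not over all genes, and all are named after their values were seen. The chemokine receptor gene Cxcr4, which holds cells in the marrow, was at 139 ± 80.4 CPM in Gata2+/+ and 30.3 ± 8.96 CPM in Gata2+/f (−2.19), and the adhesion molecule gene Pecam1 at 13.6 ± 9.48 and 54.4 ± 8.94 CPM (2.004), in an adhesion and homing list with a median of 0.27 (camera adjusted p = 0.266). The hypoxia- and stress-responsive genes Ddit4 (483 ± 248 against 83.7 ± 40.6 CPM, −2.53) and Ndrg1 (233 ± 121 against 36.4 ± 18.6 CPM, −2.68) were lower in a glycolysis and hypoxia list with a median of −0.010 (0.396). Cytochrome c, Cycs (0.90), was higher and the inhibitors of apoptosis Birc3 (−1.21) and Birc2 (−0.89) lower in an apoptosis list with a median of 0.077 (0.881). Pdia6 (87.2 ± 23.0 against 218 ± 45.5 CPM, 1.32) was higher in the unfolded protein response list, with a median of 0.31 (0.129), and Hist1h1c (284 ± 216 against 39.5 ± 9.63 CPM, −2.85) lower among replication dependent histones, with a median of −0.18 (0.487). No member passed in the RAS MAPK feedback (median −1.03, 0.202), JAK STAT target (−0.49, 0.211), inflammation and NF-kB (−0.30, 0.639), human inversion 16 AML (0.57, 0.286), p53 target (median 0.022 and mean −0.14, 0.881), ribosomal protein (median 0.00094 and mean −0.020, 0.881) or mitochondrially encoded (0.15, 0.629) lists. Some of these lists were called when 1 library was left out: the unfolded protein response without Gata2+/+ replicate 3 (adjusted p = 0.0460) or Gata2+/f replicate 7 (0.0257), replication dependent histones without Gata2+/+ replicate 6 (0.0244) and the mitochondrially encoded list without Gata2+/f replicate 9 (0.0402). In the 3 male libraries, Ddx3y stood at 138, 97.0 and 27.4 CPM and Uty at 28.5, 34.1 and 9.32 CPM (Gata2+/+ 3, Gata2+/f 7 and Gata2+/f 9), while Eif2s3y stood at 102, 103 and 89.6 CPM.

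The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. As many genes higher as in the real split (0) came in 10 of 10 splits and as many lower (0) in 10 of 10, with at most 2 in another split either way; since the real counts were 0, every split has as many, and these shares say nothing about the grouping. As many lists as the real 16 came in 2 of 10 splits, with at most 16 in another split, and as many chromosomes as the real 1 in 9 of 10, with at most 3. As many genes at an unadjusted p under 0.05 as the real 3486 came in 1 of 10 splits, and the highest other split had 1349.

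In Gata2+/f, Kit was lower while neutrophil genes were higher, a pattern that another mix of cells in the sort might give. Dilution by mature cells that do not divide would lower the proliferation list with Kit, if the leukaemia cells divided equally in both genotypes. That list had a median log2 fold change of 1.22 (SD over members 0.37), which argues against such dilution under that condition only. Whether the leukaemia cells divided equally was not tested. Within Gata2+/f the proliferation medians were 0.92, 0.48 and 0.31 in replicates 7, 9 and 11. Those of late neutrophil genes ran in the opposite order (0.63, 1.58 and 2.36), as such dilution might also give. Dilution by other cells stays open. The stem and early progenitor list had a median of −0.089 with an SD of 1.12 over members. Its distance from 0.5 of Kit's log2 fold change (−1.17) is within that SD, the margin used for this test. That SD is a spread between genes and does not measure how certain the median is, so the list does not decide the question. Unequal numbers of males and females are argued against as the cause for the neutrophil list, whose median was 3.25 with sex as a covariate against 2.86 without. The only Gata2+/+ male was replicate 3 and the only Gata2+/f female was replicate 11. Each comparison within a sex thus rests on a single mouse on one side. Mature neutrophils carried through the sort cannot be told apart from leukaemia cells with a granulocytic programme: the log2 ratio of late genes (Retnlg, Mmp8, Mmp9, Cxcr2, Il1b, Csf3r) to granule genes (Ngp, Ltf, Camp, Lcn2, Cd177) was −4.58, −4.14 and −3.05 in Gata2+/f, a range of 1.52 that carried cells of different stages may also give. The ratio was −2.03, −1.91 and −2.99 in Gata2+/+, so granule genes differed more between the groups than late genes did, though the closest libraries were nearly equal. No library of mature neutrophils gives the ratio to expect, so both sources stay open, and the genotype remains untested as a cause.

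The lower chromosome 15 genes in Gata2+/f rested on Gata2+/+ replicates 3 and 6. An effect of the genotype on the whole chromosome is argued against by Gata2+/+ replicate 5, whose interval ends at −0.0755 while those of the other 2 begin at 0.25 and 0.26. These intervals are over genes within a library and do not cover differences between mice, so the argument rests on that single mouse. GC content is argued against as the whole cause, since 91.7% of the smaller shift remained after each library's trend over transcript GC was removed. A gain of chromosome 15 in part or all of the cells of these 2 leukaemias could not be told from other causes and stays open: 53.3% of blocks of 25 genes in replicate 3 and 66.7% in replicate 6 lay above 0.5 of the log2 ratio of 3 copies to 2, short of the 75% set beforehand, with 0 blocks as far below. After the GC trend was removed, 40% of blocks in replicate 3 and 66.7% in replicate 6 lay above. The cutoff of 0.29 lay close to the shifts of the whole chromosome, 0.30 and 0.32 before that removal. An even shift along the chromosome could therefore also fall short of 75%, and the block shares do not decide the question.

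The lower median of the handling and heat shock stress list in Gata2+/f depended largely on 1 library, Gata2+/+ replicate 3. More stress in that library might give this. Without that library the median log2 fold change went from −1.44 to −0.41 and the list was no longer called (camera adjusted p = 0.399). Klf6, chosen after its values were seen, was at 8972 CPM in that library and between 189 and 941 CPM in the other 5. Not every member rested on that library. Junb had 930 and 556 CPM in Gata2+/+ replicates 5 and 6 against 119 to 249 CPM in Gata2+/f. Egr1 had 1362 and 388 CPM there against 188 to 277 CPM. For 7 of 24 members all Gata2+/f libraries lay below all Gata2+/+ libraries, and for 0 above. Over all genes tested the groups did not overlap for 29.7%, in either direction. Whether the stress arose in the mouse or during thawing and sorting was not tested, and a genotype effect on the part that remained stays open.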
